A study of Mus musculus with 6 samples.

How the data were processed

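RNA was measured by sequencing poly(A)-selected libraries from C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes when serum is lowered. Per the labels' protocols, cells were grown in 10% serum, differentiated for 3 days in 2% serum, and then either left untreated or given 10 ng/ml TWEAK, a cytokine of the TNF superfamily, for 12 h. Each group had 3 libraries, numbered by trial in the labels. Nothing in the labels says how far the trials were separate cultures, so p-values measure the spread between these libraries.

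Per the submitters' processing notes, the authors used Trim Galore 0.5.0, STAR 2.6.0c, HTSeq 0.6.1p2 and DESeq2 1.22.2 with genome build GRCm39; the settings, the annotation release and the use of strand in counting are not given in the sources used here. The deposited table lists 49592 genes with their positions. Per the file headers, it gives each library's expression as FPKM, a fragment count divided by gene length and sequencing depth. From the values, these FPKM had been scaled by the authors with a size factor per library. The same deposited table holds the authors' own comparison, with a log2 fold change and its standard error, a score (the test statistic) and an unadjusted and an adjusted p-value for each gene, per the file headers. Its mean normalized count is above 0 for 2337 genes that are at 0 in all 6 libraries, so the authors' fit held more libraries than these, which were not analysed here. The 6 libraries held a median of 50.2% of that mean. The number of per-sample columns left without a sample was 0.

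Raw counts were not used here. Because each FPKM is a whole number of reads divided by a gene length and a library factor, the reads were recovered from the values: all 126386 values above 0 came out whole within a relative tolerance of 1e-06. For 295 of the 12770 tested genes a common factor had to be chosen, among those that give a whole gene length, as the one that put the share of the deposited mean held by the 6 libraries nearest to 0.5, which is an assumption. The recovered totals were 29981045, 34318928 and 30091917 reads in TWEAK replicates 1, 2 and 3, and 33495654, 33597634 and 40920873 in untreated replicates 1, 2 and 3. The reads served for depth, for counting intervals and as an alternative unit.

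The design fixed before the data were examined named a count test for counts and, for a table of FPKM only, limma-trend on log2(FPKM + 1). The latter was therefore used, on genes with a mean FPKM of at least 0.5, with group as the only term, moderated statistics and two-sided p-values adjusted by the Benjamini-Hochberg method at 0.05 (limma 3.58.1, R 4.3.3). Every log2 fold change is TWEAK minus untreated on the log2(FPKM + 1) scale, which understates the change of genes near 0. Folds are ratios of mean FPKM. Where a group had few reads, the ratio of pooled reads per size factor is given with a 95% exact binomial interval, which covers counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 recovered the reads and drew the plots.

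A set of 21 gene lists was fixed before the data were examined, and the 20 with at least 2 tested members were tested with limma's camera at its preset correlation of 0.01, beside camera with an estimated correlation and fry. With the preset, 12 lists passed at 0.05. With an estimated correlation, limma's camera passed 0 lists, with a smallest adjusted p of 0.179 and 4 lists under 0.05 before adjustment. That correlation was estimated only in the fit with group as its only term, so differences between trials could enter it. With fry, which asks whether a list's genes move on balance in a single direction and does not compare them with other genes, 12 lists passed. These differed from the 12 of camera with the preset in 2 lists. The extracellular matrix list did not pass fry (adjusted p = 0.233), and the undifferentiated marker list did (fry adjusted p = 0.00376). Named genes followed a rule fixed at the same time: the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 value of at least 1 and no overlap between groups, up to 3 risen and 3 fallen members of each list by adjusted p, and a set of genes named in advance. Predicted gene models were left out of the largest changes. Other genes named were chosen after their values were seen. A gene that the rule names is not reported here.

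The trial numbers were taken to pair the libraries, from the data and not from the labels. Across genes, deviations from the group means correlated at 0.473, 0.218 and 0.434 between the TWEAK and untreated libraries of trials 1, 2 and 3, against at most -0.02 between libraries of different trials. Deviations from a group mean cancel out within the group, so positive values within trials push those between trials down. The values between trials are thus not separate evidence, and so few libraries can be matched in only a few ways. The pairing remains an assumption. The first principal component held 64.0% of the variance and separated the groups, and the next held 18.5% and set trial 3 apart from trials 1 and 2. All pairs of libraries in a group differed by more than sampling noise (chi-square per degree of freedom from 10.7 to 32.4).

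Alternatives covered the pseudocount, low-value filters, upper-quartile scaling, a replicate block on the trial number, a minimum fold of 1.2, and leaving out each library. Added after seeing the data were scaling to total reads, limma-voom on the recovered reads (with and without the block), smooth gene-length or GC trends removed, and both trial 3 libraries left out. All 12770 tested genes had a length and 12738 had a GC value. The fit was tested on simulated negative binomial reads for 12770 genes, all given the median dispersion of the genes with a mean above 50 reads. The changed genes were drawn from those genes, and no trial effect was simulated. The fit recovered 28.0% of 50 genes changed 1.25-fold, 80.0% of 50 changed 1.5-fold and 100.0% of those changed 2-fold or 4-fold. It made 12 false calls among 12570 unchanged genes. Recovery of genes with fewer reads was not tested.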

Results

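The transcriptomes of 6 libraries from C2C12 myotubes were compared, 3 from cultures treated with TWEAK for 12 h at 10 ng/ml and 3 from untreated cultures. C2C12 is a mouse myoblast line whose cells leave the cell cycle, fuse and assemble sarcomeres in low serum. TWEAK acts through the receptor Fn14 (gene Tnfrsf12a) and can activate both the classical and the alternative NF-kB pathway. The libraries held 29981045 to 40920873 recovered reads each. Mitochondrially encoded genes took 2.12% to 2.88% of the reads, and the 10 most abundant genes took 5.24% to 6.10%. The mitochondrial share may be too low, because mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 had very low values beside mt-Co1, as given below. The comparison addresses how TWEAK acts on gene expression while myotubes fuse, and the series title singles out Cxcl10, Mymx, alternative NF-kB and fusion.

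After 12 h of TWEAK, transcripts of 13 of 20 tested chemokine and cytokine genes, 15 of 25 NF-kB genes, 11 of 12 antigen-processing genes and 19 of 24 cell cycle genes rose, and those of 16 of 41 sarcomeric genes fell. As lists, all 5 passed limma's camera with its preset correlation and none did with an estimated correlation (adjusted p from 0.179 to 0.214 with an estimated correlation). The monocyte chemoattractant Ccl2 was at 125 ± 28.8 FPKM with TWEAK and 1.95 ± 0.526 without (mean ± SD, n = 3 per group), a 64.0-fold difference. Mymx, the small membrane protein that drives myoblast fusion, was 2.50-fold higher, while Tcap, a Z-disc protein that caps titin, was 2.91-fold lower. Of 12770 genes tested with limma, 1926 passed an adjusted p of 0.05, 1147 of them higher and 779 lower with TWEAK. A log2 fold change above 1 was reached by 99 of the genes that rose, and 22 of those that fell went below -1. With the trial number as a replicate block, 3563 genes passed, 1965 higher and 1598 lower, and these included all 1926. The number that passed was 844 without TWEAK replicate 2, 1099 without untreated replicate 1 and 1104 without untreated replicate 2; the number that rose was 741 without untreated replicate 3.

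Of 25 tested members of the pathway and its feedback inhibitors, 15 rose and 0 fell (16 and 0 adjusted over the list alone; limma's camera, adjusted p = 5.41e-11, and adjusted p = 0.179 with an estimated correlation). Nfkb2, which encodes the p100 precursor of the alternative pathway (ENSMUSG00000025225.16, GRCm39 chromosome 19, 46292759 to 46300824), was at 77.5 ± 9.18 FPKM with TWEAK and 22.0 ± 1.73 without (log2 fold change 1.77, SE 0.09, limma adjusted p = 1.44e-05). Its partner Relb rose 1.99-fold and Map3k14, the gene of the NF-kB-inducing kinase NIK, 2.09-fold. The classical subunits moved less: Rela rose 1.26-fold and Nfkb1 1.26-fold, and both calls were lost without some single libraries. For Rela the limma adjusted p was 0.0636 without TWEAK replicate 2. For Nfkb1 it was 0.0876 without that library and 0.0665, 0.0536 and 0.059 without untreated replicates 1, 2 and 3. With the replicate block and all libraries, it was 0.00158 for Rela and 0.00201 for Nfkb1. The inhibitor genes Nfkbie and Nfkbia rose 11.1-fold and 3.59-fold, and the adaptor gene Traf1 15.6-fold. The receptor gene Tnfrsf12a stood at 244 ± 36.6 FPKM with TWEAK and 246 ± 26.3 without (limma adjusted p = 0.937). Birc3, the gene of the survival factor cIAP2, lay below the expression minimum, with 207 reads against 12 (ratio 19.3, 95% interval 10.8 to 38.0).

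Chemokine and cytokine genes rose in 13 of 20 tested cases and fell in 0 (13 and 0 adjusted over the list alone; limma's camera, adjusted p = 3.6e-11, and adjusted p = 0.179 with an estimated correlation). Beside Ccl2 (chromosome 11, 81926397 to 81928279; log2 fold change 5.40, SE 0.18, limma adjusted p = 1.61e-06), its neighbour Ccl7 went from 6.80 ± 1.43 to 72.2 ± 17.9 FPKM and the membrane-bound Cx3cl1 from 6.81 ± 1.78 to 42.9 ± 14.8 FPKM. Cxcl10, a ligand of the receptor CXCR3 (ENSMUSG00000034855.14, chromosome 5, 92494497 to 92496748), was nearly absent from untreated cells and low in treated ones. It had 226 reads in the TWEAK libraries and 4 in the untreated ones, at 1.05 ± 0.236 and 0.0173 ± 0.00862 FPKM. The ratio of pooled reads was 63.3 (95% interval 24.4 to 235), and the log2 fold change on the log2(FPKM + 1) scale was 1.01 (SE 0.10, limma adjusted p = 0.00042). Leaving out any of the 3 TWEAK libraries put Cxcl10 below the expression minimum, and it overlaps Art3. Ccl5 had 216 reads against 1 (ratio 242, 95% interval 43.0 to 9610). Among adhesion receptors, 2 of 4 tested rose and 0 fell (2 and 0 adjusted over the list alone; limma's camera, adjusted p = 0.00858, and adjusted p = 0.19 with an estimated correlation). These were Vcam1, up 2.43-fold, and Icam1, with 1090 reads against 2 (ratio 611, 95% interval 169 to 5050).

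Genes of MHC class I antigen presentation rose in 11 of 12 tested cases and fell in 0 (12 and 0 adjusted over the list alone; limma's camera, adjusted p = 4.23e-12, and adjusted p = 0.179 with an estimated correlation). The immunoproteasome subunit Psmb10 rose 4.12-fold, the peptide-loading factor Tapbp 2.75-fold and the proteasome activator Psme2 2.06-fold. The H2 genes are near-identical paralogs that can share reads, so their separate values are uncertain. The remaining member, B2m, was at 322 FPKM against 256 (limma adjusted p = 0.0774, and 0.0049 with the replicate block). Of 19 tested interferon-stimulated genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone; limma's camera, adjusted p = 1.86e-05, and adjusted p = 0.179 with an estimated correlation). The largest were Bst2, up 2.45-fold, the transcription factor Irf1, up 2.22-fold, and Gbp2, up 5.11-fold from 0.259 FPKM.

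Mymx was the member of the fusion list that rose. It stood at 282 ± 8.18 FPKM with TWEAK and 113 ± 17.1 without (ENSMUSG00000079471.5, chromosome 17, 45911897 to 45913028; log2 fold change 1.32, SE 0.11, limma adjusted p = 1e-04). Mymk, which encodes the other muscle-specific fusogen, was at 646 ± 29.3 and 578 ± 41.4 FPKM (limma adjusted p = 0.262). The adhesion molecule Jam2, the integrin subunit Itga3 and the scavenger receptor Cd36 fell 1.63-fold, 1.56-fold and 1.46-fold. Of 23 tested fusion genes, 1 rose and 3 fell (2 and 5 adjusted over the list alone, 2 and 6 with the replicate block), and the list as a whole did not pass (limma's camera, adjusted p = 0.165).

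**Figure D1:**
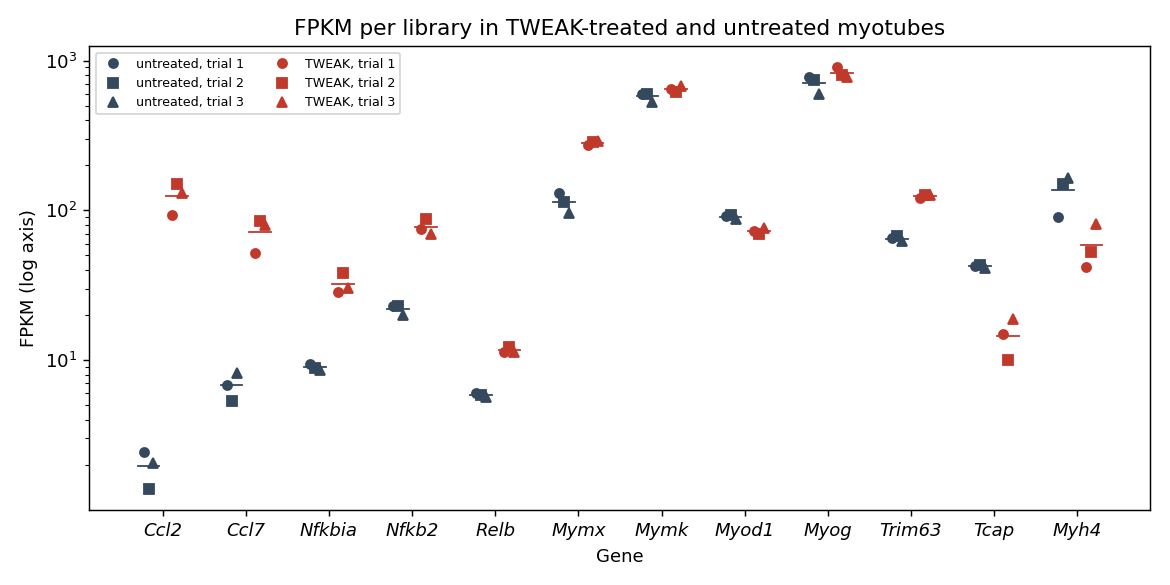
FPKM of 12 genes in each of the 6 libraries, on a log axis; points are libraries, with the marker shape giving the trial, and short lines are group means (n = 3). Ccl2, Ccl7, Nfkbia, Nfkb2, Relb, Mymx, Mymk, Myog and Trim63 lie higher in all TWEAK libraries than in all untreated ones. Myod1, Tcap and Myh4 lie lower in all TWEAK libraries. Mymk, which averages 646 against 578 FPKM, and Myog did not pass the limma threshold.

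Among 16 tested regulators, 1 rose and 5 fell (1 and 8 adjusted over the list alone, 1 and 8 with the replicate block; limma's camera, adjusted p = 0.00139, and adjusted p = 0.179 with an estimated correlation). Mef2c, a transcription factor of muscle differentiation, fell 1.75-fold. Id1 and Id3, which encode inhibitors of MyoD-family factors, fell 1.81-fold and 1.69-fold, and Msc, a repressor of that family, rose from 0.416 to 0.817 FPKM. Myod1, the myogenic determination factor, was at 72.9 ± 3.30 FPKM against 90.7 ± 3.27 (limma adjusted p = 0.0142); without TWEAK replicate 2 the adjusted p was 0.0801, and without untreated replicates 1 and 2 it was 0.0597 and 0.0579. The Msc call was lost without TWEAK replicate 1 or 2 or any untreated library, at limma adjusted p values from 0.0565 to 0.0794. Myog, which drives terminal differentiation, was at 826 ± 66.7 and 706 ± 94.6 FPKM (limma adjusted p = 0.221). With limma-voom on recovered reads and the replicate block, a setting chosen after seeing the data, its adjusted p was 0.0201; it was 0.0702 or more under the other alternatives.

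Sarcomeric and contractile genes fell in 16 of 41 tested cases and rose in 0 (19 and 0 adjusted over the list alone; limma's camera, adjusted p = 9.67e-11, and adjusted p = 0.214 with an estimated correlation). Tcap was at 14.6 ± 4.42 FPKM with TWEAK and 42.4 ± 0.920 without (log2 fold change -1.52, SE 0.17, limma adjusted p = 0.000736). The slow myosin gene Myh7 fell 2.23-fold, the cardiac actin gene Actc1 1.88-fold and the fast myosin gene Myh4 2.32-fold. The Myh4 call was lost without some single libraries. Its limma adjusted p was 0.0523 without TWEAK replicate 2 and 0.068 and 0.0536 without untreated replicates 2 and 3. It was 4.4e-07 with the replicate block and all libraries. Across the fits that left out single libraries, the Myh4 log2 fold change stayed between -1.4681 and -0.9971. The median log2 fold change of the list was -0.27, and 25 members did not pass, among them the highly expressed Mylpf, at 5226 against 5900 FPKM.

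Cell cycle genes, which are low in differentiated myotubes, rose in 19 of 24 tested cases and fell in 0 (23 and 0 adjusted over the list alone; limma's camera, adjusted p = 4.23e-12, and adjusted p = 0.203 with an estimated correlation). Ccne1, a cyclin of S-phase entry, rose from 5.25 ± 0.825 to 9.63 ± 1.16 FPKM, the replicative helicase subunit Mcm7 1.90-fold and the nucleotide-synthesis gene Tyms 1.88-fold. Markers of undifferentiated or reserve myoblasts moved apart: of 10 tested, 3 rose and 4 fell (3 and 5 adjusted over the list alone; limma's camera, adjusted p = 0.0866). Cd34 and Ccnd1 rose 2.01-fold and 1.92-fold with Msc, while Id1, Id3, Heyl and Myf5 fell. The mean and median of this list were both below 0, and the list passed fry (adjusted p = 0.00376). Leaving out TWEAK replicate 2 or 3, or untreated replicate 1 or 3, ended the Ccnd1 call (limma adjusted p from 0.0536 to 0.0727). The Msc call ended without TWEAK replicate 1 or 2 or any untreated library (up to 0.0794). With the replicate block and all libraries, the limma adjusted p was 4.72e-07 for Ccnd1 and 0.0116 for Msc.

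**Figure D2:**
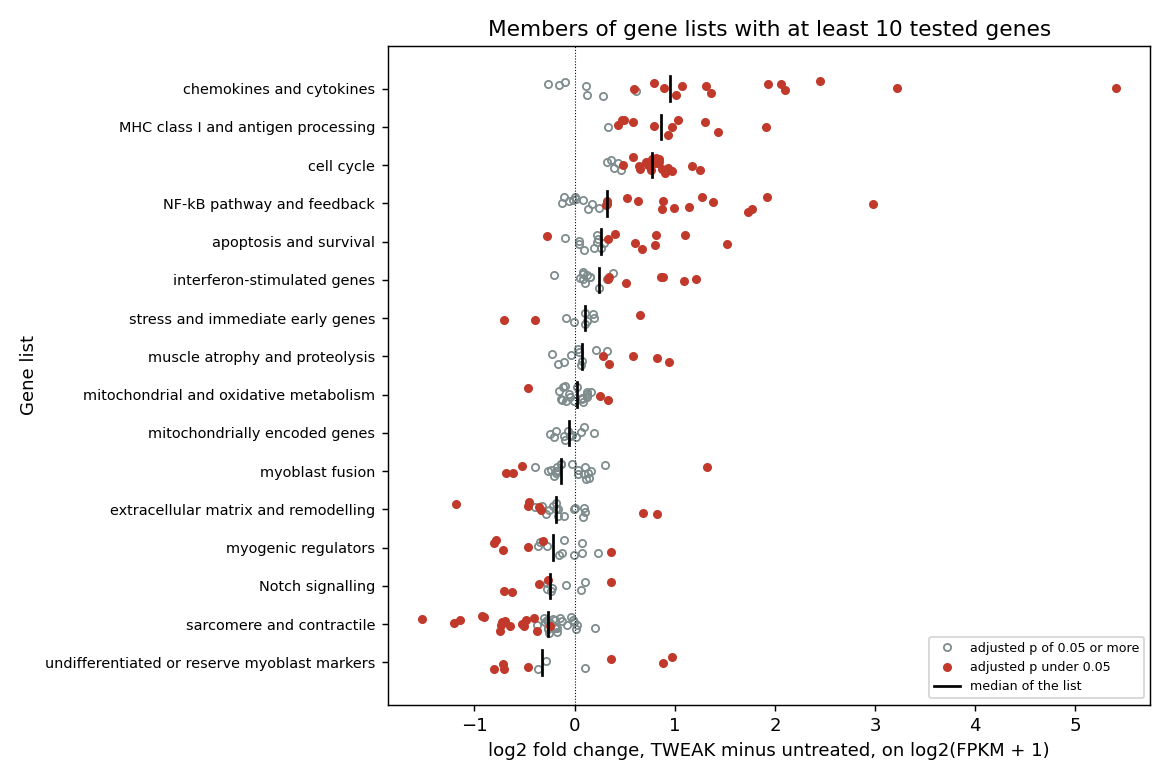
Log2 fold change (TWEAK minus untreated, log2(FPKM + 1) scale, horizontal axis) of each tested member of the gene lists with at least 10 tested genes; filled points passed a limma adjusted p of 0.05, open points did not, and black lines are list medians. The medians run from -0.33 for undifferentiated or reserve myoblast markers to 0.95 for chemokines and cytokines.

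Of 15 tested atrophy and proteolysis genes, 5 rose and 0 fell (6 and 1 adjusted over the list alone; limma's camera, adjusted p = 0.0174, and adjusted p = 0.179 with an estimated correlation). The list no longer passed without TWEAK replicate 1 (adjusted p = 0.0655). Trim63, the gene of the muscle ubiquitin ligase MuRF1, was at 125 ± 4.31 FPKM against 64.8 ± 2.59, and Fbxo32, the gene of the ligase atrogin-1, at 18.2 ± 2.63 against 11.7 ± 1.07. Cebpd rose 2.14-fold. Apoptosis and survival genes rose in 8 of 19 tested cases and fell in 1 (11 and 1 adjusted over the list alone; limma's camera, adjusted p = 7.76e-06, and adjusted p = 0.19 with an estimated correlation). The inflammatory caspase gene Casp4 rose 4.58-fold, the pro-apoptotic Bid 1.79-fold and the stress-response gene Gadd45b 1.76-fold. The caspase inhibitor gene Xiap fell from 7.71 to 6.18 FPKM (limma adjusted p = 0.0496). It no longer passed without TWEAK replicate 2 or 3 or any untreated library (from 0.0696 to 0.141).

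Nuclear genes of mitochondrial and oxidative metabolism mostly did not pass: 2 of 21 rose and 1 fell (2 and 1 adjusted over the list alone; limma's camera, adjusted p = 0.863). Tfam, which maintains mitochondrial DNA, and the fatty acid oxidation gene Acadl rose, by log2 fold changes of 0.33 and 0.26. The glucose transporter gene Slc2a4 fell 2.31-fold (log2 fold change -0.47), from 0.945 to 0.409 FPKM, close to the expression minimum. Without TWEAK replicate 2 these calls were lost, at limma adjusted p values of 0.0774, 0.117 and 0.0561, and without untreated replicate 2, at 0.0669, 0.132 and 0.0574. The Tfam call was also lost without untreated replicate 1 (0.0563), and the Acadl call without TWEAK replicate 3 (0.0666) or untreated replicate 1 or 3 (0.142 and 0.0591). Ppargc1a, a regulator of mitochondrial biogenesis, lay below the expression minimum at 0.268 ± 0.0515 FPKM against 0.483 ± 0.0855; in the authors' deposited table its log2 fold change is -0.85 (adjusted p = 0.00178). Of 12 mitochondrially encoded genes, limma called 0, with 0 under an unadjusted p of 0.05, 0 adjusted over the list alone and 0 on recovered reads (limma's camera, adjusted p = 0.471); mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 were at 3.27, 2.83, 1.47 and 0.920 FPKM in untreated cells, against 5647 for mt-Co1, so their values are uncertain.

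Extracellular matrix genes fell in 5 of 22 tested cases and rose in 2 (6 and 2 adjusted over the list alone, 9 and 2 with the replicate block; limma's camera, adjusted p = 0.0166, and adjusted p = 0.498 with an estimated correlation). The list did not pass fry (adjusted p = 0.233). It lost its camera call without TWEAK replicate 1 (adjusted p = 0.119), TWEAK replicate 2 (0.0767) or untreated replicate 3 (0.0753). Timp3, an inhibitor of matrix metalloproteinases, fell 2.33-fold and the collagen genes Col1a1 and Col5a1 1.38-fold and 1.39-fold, while Timp1 rose 1.62-fold. Notch genes fell in 4 of 12 tested cases and rose in 1 (6 and 1 adjusted over the list alone, 7 and 1 with the replicate block; limma's camera, adjusted p = 0.0128, and adjusted p = 0.214 with an estimated correlation). The Notch effector gene Heyl fell 1.97-fold, the ligand gene Dll1 and Hes6 fell by 0.26 and 0.35 on the log2 scale, and Rbpj, the pathway's DNA-binding factor, rose by 0.37. Leaving out TWEAK replicate 2, untreated replicate 1 or untreated replicate 2 ended the calls of Timp1, Dll1, Hes6 and Rbpj, with limma adjusted p values of up to 0.064, 0.137, 0.146 and 0.147. Dll1 was also lost without TWEAK replicate 3 (0.0755) or untreated replicate 3 (0.0539), and Rbpj without TWEAK replicate 1 (0.0789) or untreated replicate 3 (0.111). With the replicate block and all libraries, the limma adjusted p was 4.43e-05 for Timp1, 0.00712 for Dll1, 0.00695 for Hes6 and 0.00241 for Rbpj.

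Stress and immediate early genes rose in 1 and fell in 2 of 10 tested cases (2 and 2 adjusted over the list alone and with the replicate block; limma's camera, adjusted p = 0.683): the AP-1 gene Junb rose 1.58-fold, and Fos and Atf3 fell 1.63-fold and 2.00-fold. Most markers of other cell types lay below the expression minimum. Of 2 tested macrophage and leukocyte markers, Cd14 rose 1.48-fold (1 adjusted over the list alone; limma's camera, adjusted p = 0.244 for the list). Of 3 adipocyte markers, Pparg fell 1.51-fold (1 adjusted over the list alone, 2 with the replicate block; limma's camera, adjusted p = 0.212). Neither of the 2 osteoblast markers tested with limma passed (1 at an unadjusted p under 0.05, 0 adjusted over the list alone, 0 called on recovered reads; limma's camera, adjusted p = 0.391), nor did the 1 endothelial marker (0, 0 and 0 likewise). The Cd14, Pparg and Fos calls were lost without untreated replicate 1 (limma adjusted p of 0.0537, 0.091 and 0.0662). Cd14 and Pparg were also lost without TWEAK replicate 2 (0.054 and 0.0996), and Pparg without untreated replicate 3 (0.0712).

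Outside the lists, the largest rises were in Xcl1, a lymphocyte chemokine gene with 337 reads against 1 (ratio 378, 95% interval 67.4 to 15000), the complement gene C3, with 2075 reads against 9 (ratio 259, 95% interval 136 to 566), and Ucma, with 497 against 24 (ratio 23.2, 95% interval 15.4 to 36.6). Ache, the acetylcholinesterase gene, and Colq, which anchors that enzyme at the synapse, rose 12.4-fold and 6.42-fold. The largest falls included Abra, an actin-binding activator of SRF signalling, down 3.03-fold, Fgf5, down 4.02-fold, the Wnt inhibitor gene Nkd2, down 3.33-fold, Map3k7cl, down 2.85-fold, the neuronal pentraxin Nptx1, down 2.78-fold, Myh7b, down 2.75-fold, and the tetraspanin Tspan8, down 2.68-fold. Some named genes overlap another gene, and the use of strand in counting is not given in the sources used here, so their values are uncertain. The largest shares of joint reads taken by the overlapping genes were 71.4% at Myh7b, 68.7% at Mcm7, 66.1% at Cxcl10, 58.3% at Junb, 58.1% at Cebpd, 50.3% at Bid, 33.0% at Ccnd1, 19.8% at Tapbp and 15.5% at Msc. In the authors' deposited table, 3151 genes lie under an adjusted p of 0.05, 1716 higher and 1435 lower; of the 2930 among the genes tested here, 1841 also passed here, all 1841 with the same sign, and 85 passed here but not there.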

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

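The count below comes from deposited data outside the comparison of the 6 libraries, and its test was chosen after the values were seen. In 2337 of the 49592 listed genes, FPKM was 0 in all 6 libraries, while the authors' mean normalized count over their libraries was above 0. The highest such mean was 1.87 (Pnliprp2) and the median 0.0915. Libraries other than these 6 entered that mean and were not analysed here; no explanation was tested.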

How the results depend on the processing

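Scaling to total reads, limma-voom, length and GC trends and leaving out trial 3 were tests chosen after the data were seen; the rest were planned. The planned edgeR settings (RLE and upper-quartile factors, a block, a minimum fold) and DESeq2 were not run, because the deposited values are FPKM; limma counterparts took the place of all but RLE and DESeq2. The number of genes changed, risen and fallen was 801, 499 and 302 with no filter on low values, where more genes are tested, and 276, 201 and 75 against a minimum fold of 1.2, a stricter hypothesis. It was 3563, 1965 and 1598 with the replicate block, which changed no call of a list test or of a gene named by the rule set in advance. With the block it was 3534, 1975 and 1559 after removing the length trend, 3997, 2167 and 1830 after removing the GC trend, and 4018, 2116 and 1902 with limma-voom. Scaling moved the balance: 991 rose and 928 fell with upper-quartile scaling, and 1444 and 663 with scaling to total reads. Without 1 library, with fewer samples, the number changed, risen and fallen ranged from 844 to 2101, 501 to 1266 and 343 to 835. The extracellular matrix list lost its camera call with no filter (limma adjusted p = 0.227), and ranged from 0.000142 to 0.119 without 1 library; the atrophy list ranged from 0.00837 to 0.0655. The undifferentiated marker list passed camera with at least 5 CPM in 3 libraries (0.0187). It also passed, just under the threshold, without TWEAK replicate 3 (0.05 after rounding), and ranged from there to 0.157 without 1 library. Lists that did not pass changed direction in some settings. Macrophage markers did so with no filter (camera adjusted p = 0.745). Mitochondrial metabolism did so after removing the length trend (0.645, and 0.656 with the replicate block) and without trial 3 (0.598). It also did so without TWEAK replicate 3 (0.314) or untreated replicate 1 (0.868), and ranged from 0.314 to 0.914 without 1 library. Mitochondrially encoded genes did so without untreated replicate 3 (range 0.0694 to 0.963). Tnfrsf12a, which did not pass, had log2 fold changes of 0.0111 with total-read scaling and from -0.14 to 0.0602 without 1 library (0.0602 without TWEAK replicate 1, 0.0221 without TWEAK replicate 2, 0.0563 without untreated replicate 2). Beyond fewer genes or samples, the cause was not tested. Of 75 called named genes, 17 lost the call without at least 1 library, 17 with no filter on low values, 26 against a minimum fold of 1.2 and 7 without trial 3. With no filter these included Atf3, Heyl, Fbxo32 and Cd34 (limma adjusted p of 0.0833, 0.0528, 0.0554 and 0.0805), which kept their calls without any 1 library. Calls also ended for Xiap and Dll1 with total-read scaling (0.0784 and 0.0567), Rbpj with upper-quartile scaling (0.0589), and Msc and Xiap after removing the length trend (0.0583 and 0.107, and 0.0553 for Xiap with the replicate block as well). Depth limits genes such as Cxcl10 and Ccl5, with 4 and 1 untreated reads.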

Other observations

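Tests of the share of differentiated cells, of cell cycle exit genes, of H2 paralogs and of an interferon loop were chosen after the results were seen, and so were the gene groups of the next paragraph and the length trend by trial.

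Of 13 Z-disc and stretch-responsive muscle genes, 12 fell by limma. These genes were picked after falls of Abra and Tcap had been seen, and Tcap is also in the contractile list, so the count describes them and tests nothing. Csrp3 was at 15.2 ± 1.59 FPKM with TWEAK and 35.2 ± 3.76 without (n = 3), Nrap at 28.1 ± 2.96 against 59.5 ± 5.04, and Ankrd23 at 58.3 ± 11.3 against 119 ± 2.36; Flnc, at 110 against 144 FPKM, had a limma adjusted p of 0.141, and 0.00187 with the replicate block. At the neuromuscular junction, Ache and Colq rose and the receptor kinase gene Musk fell (17.7 ± 1.85 against 24.4 ± 0.779 FPKM), while 9 of 12 tested genes did not pass, among them the acetylcholine receptor genes Chrna1 (293 ± 33.9 against 336 ± 9.20) and Chrnd (126 ± 11.5 against 144 ± 6.93). The metal-binding genes Mt1 and Mt2 rose, Mt2 from 150 ± 6.08 to 449 ± 80.1 FPKM. The ligand gene Bmp4 and its antagonist gene Nog fell with Id1 and Id3, Bmp4 from 33.7 ± 4.13 to 22.1 ± 2.12 FPKM and Nog from 2.36 ± 0.863 to 0.635 ± 0.243 FPKM; of the 3 related genes also looked up, Id2, Smad6 and Fst, none passed (limma adjusted p of 0.966, 0.285 and 0.187, and 0.00631 for Fst with the replicate block).

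Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes changed as the real split: the real split itself, at 1926 by limma, against at most 0 for the others (3871 against at most 1057 at an unadjusted p under 0.05). The 4 splits that part all 3 pairs, fitted with the replicate block, gave 3563 for the real one and at most 0 for the others (at most 72 unadjusted). With 10 splits the share cannot go under 0.05.

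Of the tested genes, 16 of 41 sarcomere genes fell and 19 of 24 cell cycle genes rose, and neither list passed limma's camera with an estimated correlation (adjusted p = 0.214 and adjusted p = 0.203 with an estimated correlation). Removing the gene length trend with the replicate block left the sarcomere median at -0.30 (quartiles -0.45 and -0.20, against -0.27 before; limma's camera with its preset correlation, adjusted p = 3.96e-12), and the cell cycle median at 0.77 (quartiles 0.56 and 0.84; adjusted p = 1.74e-20), which argues against length as the whole cause. A lower share of differentiated cells would raise all undifferentiated markers alike, yet of 10 tested, 3 rose and 4 fell past the threshold. The bar for this test was set after these falls were known, and a marker may also change within cells. The test therefore cannot decide whether that share changed. Fewer cell cycle exits stay open: of the 5 exit genes Cdkn1a, Cdkn1c, Rb1, Cdkn2c and Myog, 2 fell past the threshold with the replicate block, Cdkn1c and Rb1 (limma adjusted p of 0.266 and 0.0512 without it). A response to TWEAK may underlie the shift, which is a hypothesis.

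Of 12 tested MHC class I genes 11 rose, B2m did not pass (limma adjusted p = 0.0774), and the list did not pass limma's camera with an estimated correlation (adjusted p = 0.179 with an estimated correlation). Reads shared between H2 paralogs do not account for this, since 7 of the 8 tested members outside the H2 family rose. An interferon loop through the complex ISGF3 would raise its targets, and 0 of 7 tested (Ifit2, Ifit3, Isg15, Irf9, Rtp4, Stat2 and Xaf1) rose by limma, with 0 at an unadjusted p under 0.05, 0 with the replicate block and 0 on recovered reads. These data are thus in line with induction without that loop at 12 h, which remains a hypothesis, and direct NF-kB action on these genes was not tested.

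Longer genes were lower with TWEAK (Spearman -0.255 between log2 fold change and log2 length, across genes, which are not independent replicates). Among the 3193 shortest genes 359 rose and 106 fell, and among the 3190 longest genes 166 rose and 327 fell. The pseudocount does not produce the trend, since on recovered reads the correlation was -0.243. Nor do the genes past the threshold alone carry it, since without them the correlation was -0.249. A library length bias unrelated to TWEAK may be part of it, because the slopes of log2 value per doubling of length lay 0.0117 apart between the groups, less than the 0.0689 range within the TWEAK group; the correlation of the pair difference was -0.372 in trial 3, -0.122 in trial 1 and -0.135 in trial 2, and -0.141 without trial 3.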
